A study of Danio rerio with 6 samples.

How the data were processed

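Total RNA of whole zebrafish embryos at 72 hours post fertilization, raised at 28 °C, was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited value table holds 1 intensity per probe set and array, a MAS5 signal on a linear scale, and MAS5 is named in the submitters' processing notes without a version. MAS5 combines the probes of a probe set on 1 array at a time and scales each array to a common trimmed mean, and from the values the 2%-trimmed mean was 500.1 on every array. The table carries no detection calls, so low signals cannot be separated from background, and the number of arrays limits the precision. The authors also deposited 3 tables of fold ratios between the groups. From the values these list only ratios of at least 2 or at most 0.5, and how the replicates were combined is not given in the sources used here. Their ratios were used only to describe the overlap. The direction of each of the 3 tables was taken from its match with the value table.

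Of 15617 probe sets, 10802 carried 1 gene symbol in the platform annotation, 135 several and 4680 none. Symbols were updated by gene number through the gene table of assembly GRCz12tu, which matched 10718 and changed 1. No gene was named from a probe set with several symbols. The probe sets of col10a1a, ctrb.1, dla, elavl3, fthl28, krt91, pde6ha, runx2a and sox3 share a cluster name with a probe set of another gene, so the identity of these genes is less certain. No coordinates are given, since the array names no build. Different probe sets of a gene were not averaged, and the one with the highest mean stands for the gene.

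Signals were transformed as log2(signal + 32), so fold changes are on that scale and understate those of low genes. The 115 control probe sets and the 25% of probe sets with the lowest mean over the arrays were left out, which left 11626. No further normalization was applied. The fit used lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with all 6 arrays in 1 model of 3 groups, 3 residual degrees of freedom and 5.31 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The labels call the samples biological replicates, and p-values measure only the spread between these pools of embryos. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so p-values come from limma's model.

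The 25 gene lists were written before the data were examined and held 1102 entries, of which 556 had a tested probe set. They were, besides 1 list that is not reported here but counts in the adjustment and in totals of lists and named genes, estrogen receptors and estrogen response, Notch pathway, lateral line and hair cell, neurogenesis, glia and myelin, interferon response, inflammation, stress and heat shock, cell cycle, lens crystallin, photoreceptor, exocrine pancreas, liver, intestine, cartilage and bone, heart, skeletal muscle, red blood cell, pigment cell, hatching gland and yolk, ionocyte, epidermis, circadian clock and sterol synthesis. Each was tested with camera at a preset correlation between genes of 0.01, with adjustment over all 75 list tests. With an estimated correlation none of the list calls held. The list tests compare a list with the other genes and do not measure the spread between arrays. Intervals over arrays come from a fit by group of the mean over a list's members, with 3 residual degrees of freedom.

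Named genes followed a rule written in advance. They were, per comparison, the fixed genes esr1, esr2a, esr2b and notch3 among others, the 10 largest rises and 10 largest falls among called probe sets with 1 symbol and groups that do not overlap, and up to 3 called members of each list. Where fewer than 10 probe sets were called, the 10 smallest unadjusted p were given instead. The genes hbae3 and hbbe2 were added after their values were seen. Groups of 2 arrays that do not overlap arise by chance in 33.3% of unchanged probe sets, and 48%, 63.5% and 55% were found in the 3 comparisons.

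The pipeline was tested on simulated data with the real probe sets' means, variances drawn from the fitted prior, and 200 changed probe sets among 11626. In the simulated comparison of ERbeta2 MO with coMO, 87% of changes of 2 on the log2 scale and 12% of changes of 1 were recovered, with 7 calls without a change. A list shifted by 1 was called in both comparisons that held it, and 0 of 73 other list tests were called. The simulated probe sets were independent of each other. The list result therefore does not check calls for correlated genes, and the estimated correlation was 0.62 for photoreceptor and 0.74 for exocrine pancreas.

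Alternatives fixed before the data were examined were pseudocounts of 1 and 100, no filter and a filter that left 7751 probe sets, median centring, quantile normalization, a constant and a robust prior, fits of only the 4 arrays compared, the replicate number as a block, leaving out each array, and, for lists, an estimated correlation and fry. A fit that leaves a group with 1 array assumes that it varies like the others. Alternatives added after seeing the data were the log2 GAPDH 3'/5' ratio as a covariate and a fit without both ERbeta2 MO replicate 1 and coMO replicate 2, which left the ERbeta2 MO and coMO arrays with the closest ratio beside both uninjected arrays, whose ratio was lower.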

Results

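Gene expression was measured in whole zebrafish embryos at 72 hours post fertilization on 6 Affymetrix arrays. Eggs were injected, up to the 4 cell stage, with a morpholino that blocks translation of the estrogen receptor ERbeta2 (ERbeta2 MO) or with a standard control morpholino (coMO), both at 15 uM, and a further group was left uninjected. A morpholino is an antisense oligomer that binds an mRNA. Each of the 3 groups had 2 arrays, called biological replicates in the labels, made from eggs pooled over several aquaria. The series title names a role of ERbeta2 in neuromasts, the sensory organs of the lateral line. The 2%-trimmed mean signal was 500.1 on all arrays, and the median signal lay between 196.67 and 220.4. The first principal component held 61.9% of the variance and placed both ERbeta2 MO arrays at one end (-45.2 and -39.8), the uninjected arrays at the other (40.3 and 31.9) and the coMO arrays between them (-4.68 and 17.5).

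Control probe sets at the 2 ends of a transcript gave these ratios. The GAPDH 3'/5' ratio was 2.76 and 2.01 in ERbeta2 MO, 1.95 and 1.23 in coMO, and 1.32 and 1.24 in uninjected embryos. The acta1 ratio was 8.92 and 13.5 in ERbeta2 MO, 21.8 and 10.8 in coMO, and 3.54 and 4.26 in uninjected embryos. On the log2 scale the GAPDH ratio of ERbeta2 MO exceeded that of coMO by 0.61 (95% interval -0.449 to 1.66 over arrays) and that of uninjected embryos by 0.88 (-0.179 to 1.93), and the acta1 ratio of coMO exceeded that of uninjected embryos by 1.98 (0.411 to 3.55). The acta1 ratio of ERbeta2 MO differed from that of coMO by -0.48 (-2.05 to 1.09). The ratio of dap, a bacterial transcript spiked into the RNA before labelling, differed by -0.16 from coMO (-1.03 to 0.716) and by -0.00364 from uninjected embryos (-0.876 to 0.869). A higher ratio is usual where RNA is less intact or less completely copied. The GAPDH ratio was higher on both ERbeta2 MO arrays than on the other 4.

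**Figure D1:**
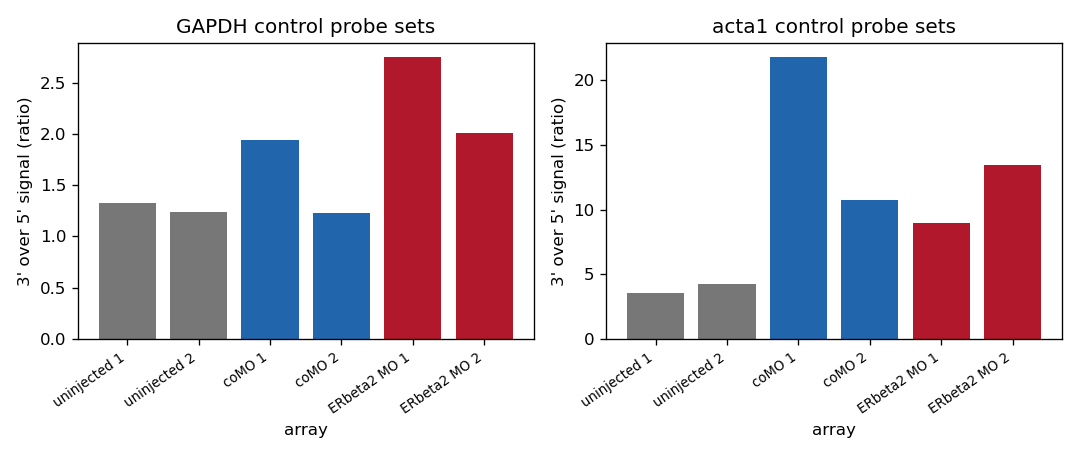
Bars give the 3'/5' signal ratio of the GAPDH (left) and acta1 (right) control probe sets on each of the 6 arrays, coloured by group. Both ERbeta2 MO arrays (2.76 and 2.01) lie above the others for GAPDH, whereas a coMO array is highest for acta1 (21.8).

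The first question was what the targeted morpholino changed beyond the control morpholino. In ERbeta2 MO embryos 18 of 35 photoreceptor genes were called lower than in coMO embryos, as were 4 of 17 exocrine pancreas, 7 of 22 intestine, 6 of 38 liver and 6 of 19 cartilage and bone genes. As lists these passed at a preset correlation between genes but not with an estimated correlation (adjusted p = 0.49, 0.54, 0.43, 0.55 and 0.49). The latter test rests on 3 residual degrees of freedom, so a lost call does not by itself show correlation between genes. The embryonic beta globin gene hbbe3 and 3 of 42 stress and heat shock genes were called higher. The cone transducin gene gnat2 fell 19-fold, from a mean signal of 3826 ± 1480 (SD, n = 2) in coMO to 224 ± 235 (SD, n = 2) in ERbeta2 MO, and hbbe3 rose 23.6-fold, from 128 ± 121 to 3197 ± 734 (SD, n = 2 each). Of 11626 probe sets tested with limma, 264 passed an adjusted p of 0.05, with 76 higher and 188 lower in ERbeta2 MO. Fold changes are on the log2(signal + 32) scale, which understates those of low genes.

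The 35 photoreceptor genes tested had a median log2 change of -2.0, with 18 called lower, 0 called higher and 17 that did not pass. Adjusted over the list alone, 27 were lower and 2 higher. The preset-correlation test of the list gave an adjusted p of 1.9e-14, and the call was lost with an estimated correlation (adjusted p = 0.49). The green cone opsin gene opn1mw1 fell by 4.11 on the log2 scale (SE 0.713, adjusted p = 0.0371), the cone phosphodiesterase genes pde6c and pde6ha changed by -3.75 and -3.72, and the ultraviolet and blue opsin genes opn1sw1 and opn1sw2 by -3.43 and -3.48. The phototransduction genes gnb3b, gngt2b and rcvrn3 changed by -3.42, -3.36 and -3.19. The ERbeta2 MO arrays differed from each other here, with opn1mw1 signals of 198 and 1532, yet both lay below the coMO signals of 8605 and 12374.5. Without ERbeta2 MO replicate 1 the changes were -2.73 for opn1mw1, -2.49 for pde6c, -2.19 for opn1sw2, -2.12 for opn1sw1 and -2.15 for gngt2b. The GAPDH 3'/5' ratio moved with this group, at 2.76 and 2.01 in ERbeta2 MO against 1.95 and 1.23 in coMO, whereas the acta1 ratio was 8.92 and 13.5 against 21.8 and 10.8. The list median was -1.23 with the GAPDH ratio as a covariate and -1.17 without both ERbeta2 MO replicate 1 and coMO replicate 2.

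Genes of the digestive organs formed the next group. In the exocrine pancreas list the median log2 change was -1.76, and 4 of 17 genes were called lower (13 adjusted over the list alone). The list had an adjusted p of 7.3e-09, and 0.54 as the adjusted p with an estimated correlation. The digestive protease genes ctrb.1, prss1 and ctrl changed by -3.01, -2.27 and -2.2. In the intestine list the median was -0.76, with 7 of 22 genes called lower (11 adjusted over the list alone) and an adjusted p of 7.3e-09, against an adjusted p of 0.43 with an estimated correlation. The intestinal fatty acid binding protein gene fabp2 fell by 2.36 (SE 0.287, adjusted p = 0.014), the brush border gene vil1 changed by -2.28 and cldn15la by -2.19. The liver list had a median of -0.51, with 6 of 38 genes called lower (10 adjusted over the list alone), an adjusted p of 7.6e-06 and an adjusted p of 0.55 with an estimated correlation. Its largest changes among called genes were -3.04 for the liver fatty acid binding protein gene fabp10a, -2.74 for uox and -1.90 for hgd. The liver median was -0.77 without ERbeta2 MO replicate 1, -0.80 without coMO replicate 1 and -0.27 without coMO replicate 2. The GAPDH ratios of 2.76 and 2.01 against 1.95 and 1.23 moved with these groups too. The liver median was nevertheless larger in size without ERbeta2 MO replicate 1, the array at 2.76. With that ratio as a covariate the medians were -0.95 for exocrine pancreas, -0.83 for intestine and -0.35 for liver, and without both ERbeta2 MO replicate 1 and coMO replicate 2 they were -0.86, -0.80 and -0.43.

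Lists of skeletal and skin genes passed as lower too. In the cartilage and bone list 6 of 19 genes were called lower (8 adjusted over the list alone) with a median of -0.45, an adjusted p of 3.7e-05 and an adjusted p of 0.49 with an estimated correlation. The cartilage matrix gene matn1 changed by -2.79 and the hypertrophic cartilage collagen gene col10a1a by -2.02. The probe set annotated as runx2a fell by 1.17, but it shares its cluster name with a probe set of a collagen gene and its identity is in doubt. The other runx2a probe set changed by -0.0367 and was not called. In the epidermis list 3 of 36 genes were called lower (9 lower and 1 higher adjusted over the list alone) with a median of -0.56 and an adjusted p of 3.6e-05, and the adjusted p was 0.61 with an estimated correlation. The keratin gene krt15 changed by -2.16, and the fin fold genes and2 and and3 by -1.21 and -1.11. Without ERbeta2 MO replicate 2 the epidermis median was 0.01 (adjusted p = 0.773), so that call rested on 1 array. The median was -1.08 without ERbeta2 MO replicate 1 and -0.38 without coMO replicate 2. The GAPDH ratio (2.76 and 2.01 against 1.95 and 1.23) moved with the cartilage and ionocyte groups, whose medians with that ratio as a covariate were -0.41 and -0.25. The epidermis group did not follow it, since the ERbeta2 MO array with the higher ratio had the smaller change and the median was -0.84 (adjusted p = 1.01e-10) with the ratio as a covariate. Without both ERbeta2 MO replicate 1 and coMO replicate 2 the medians were -0.40 for cartilage and bone, -0.27 for ionocyte and -0.95 for epidermis. In the ionocyte list 1 of 14 genes was called lower, the sodium pump gene atp1a1a.4 (-1.11), with a median of -0.49, an adjusted p of 6e-04 and 0.43 as the adjusted p with an estimated correlation. In the sterol synthesis list 1 of 15 genes was called lower (4 adjusted over the list alone), fads2 (-1.25), a fatty acid desaturase gene, with a median of -0.33, an adjusted p of 0.0018 and 0.43 as the adjusted p with an estimated correlation.

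Among genes that rose, rps27l, a ribosomal protein-like gene, changed by 2.37 (SE 0.319, adjusted p = 0.018). Of 9 interferon response genes, isg15 alone was called higher (2.09; 2 genes adjusted over the list alone), with a list median of 0.45, an adjusted p of 0.019 and an adjusted p of 0.55 with an estimated correlation. Of 23 inflammation genes, the metalloproteinase gene mmp9 (2.64) and the cytokine signalling inhibitor gene socs3b (1.73) were called higher (7 adjusted over the list alone), with a list median of 0.39, an adjusted p of 0.019 and an adjusted p of 0.61 with an estimated correlation. The interferon and inflammation calls were lost without ERbeta2 MO replicate 1 (medians 0.05 and 0.10, adjusted p = 0.117 and 0.314), without coMO replicate 1 (medians 0.22 and 0.14, adjusted p = 0.149 and 0.232) and without both ERbeta2 MO replicate 1 and coMO replicate 2 (medians 0.27 and 0.29, adjusted p = 0.055 and 0.0758). The interferon call was also lost with a pseudocount of 1, although the median was 0.43 (adjusted p = 0.118), and with no filter (median 0.10, adjusted p = 0.153). The inflammation median was 0.80 without ERbeta2 MO replicate 2. The GAPDH ratios (2.76 and 2.01 against 1.95 and 1.23) moved with these groups as well, and with that ratio as a covariate both lists still passed (0.39, adjusted p = 0.00738, and 0.32, adjusted p = 0.0263). In the stress and heat shock list 3 of 42 genes were called higher, the stress transcription factor gene atf3 (2.18), vegfaa (1.2) and atf4b (1.02), and 5 were higher and 5 lower adjusted over the list alone, but the list did not pass (adjusted p = 0.99) and its median (-0.05) had the sign opposite to its mean (0.03) and its test. With each array centred on its median, which shifted the median change of all probe sets by 0.07 here and by 0.12 for ERbeta2 MO against uninjected, the stress list median was 0.02, and it was -0.24 (adjusted p = 0.0375) without ERbeta2 MO replicate 1 and 0.12 (adjusted p = 0.0315) without ERbeta2 MO replicate 2.

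In the red blood cell list 3 of 13 genes were called higher, hbbe3 (4.56, SE 0.48, adjusted p = 0.0111), the anion exchanger gene slc4a1a (2.45) and hbaa1 (1.28), with a median of 0.33, an adjusted p of 0.0032 and an adjusted p of 0.43 with an estimated correlation. The abundant embryonic globin genes hbae3 and hbbe2 had changes of 0.25 and 0.12 that did not pass (adjusted p = 0.596 and 0.824). The hbbe3 call was lost without coMO replicate 2 (3.70, adjusted p = 0.142) and with the GAPDH ratio as a covariate (3.31, adjusted p = 0.261). Further genes among the largest rises were zgc:172053 (3.09), bmb (2.46), c6.2, a complement component gene (2.32), and igfbp1a, an insulin-like growth factor binding protein gene (2.19).

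**Figure D2:**
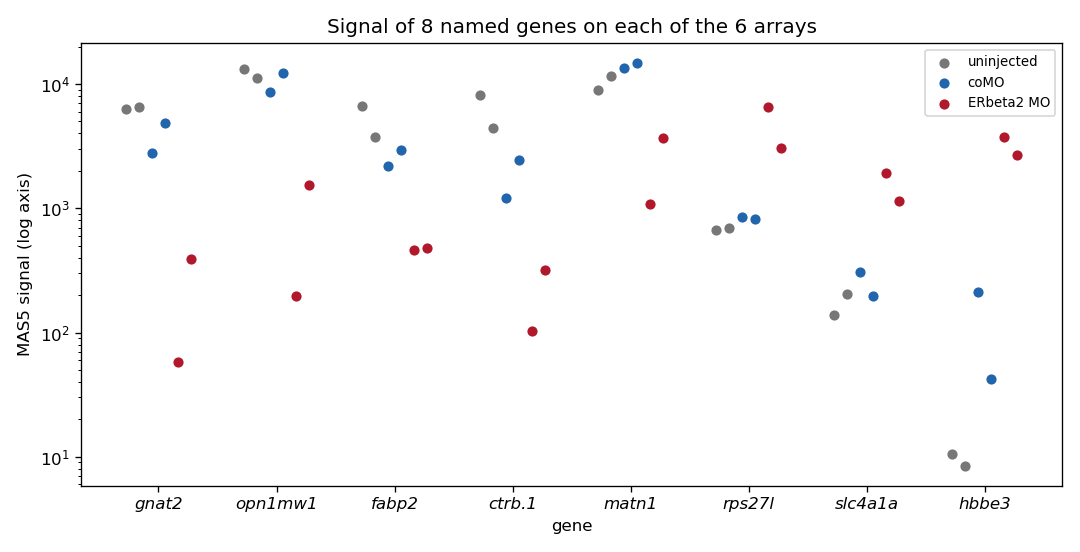
Points give the MAS5 signal of 8 named genes on each of the 6 arrays, on a log axis, with 2 arrays per group and colours for the groups. In each gene the ERbeta2 MO points lie apart from the other 4, from hbbe3 (3716 and 2678 against at most 213) to gnat2 (58.2 and 390 against at least 2783).

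The receptor genes themselves were at low signal and lay below the filter. Which of esr2a and esr2b encodes the targeted receptor was not resolved here, so neither is taken as the target. The signal of esr2b was 48.5 and 46.7 in ERbeta2 MO, 61.2 and 53.5 in coMO, and 57.2 and 55.3 in uninjected embryos. That of esr2a was 70.9 and 94.9, 62.1 and 54.9, and 51.8 and 89.6 in the same order, and that of esr1 15.9 and 54.8, 18 and 20.2, and 30 and 21.9. With no filter the changes against coMO were -0.17 for esr2b, 0.34 for esr2a and 0.34 for esr1, none of which passed (adjusted p = 0.756, 0.567 and 0.623). A translation blocker need not change the mRNA of its target, so these signals do not check the labels. In the list of estrogen receptors and estrogen response, igfbp1a was called higher and shbg (-1.48), a sex steroid binding globulin gene, and agr2 (-1.16) lower among 8 genes. That list did not pass (median -0.39, adjusted p = 0.27).

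In the Notch pathway list the ligand gene dlb was called higher (1.26, SE 0.229, adjusted p = 0.0412) among 26 genes (4 higher adjusted over the list alone), and notch3 had a change of 0.47 that did not pass (adjusted p = 0.278). The list median was 0.17 with an adjusted p of 0.022, and the adjusted p was 0.55 with an estimated correlation. Without ERbeta2 MO replicate 2 (median 0.12, adjusted p = 0.085) or coMO replicate 2 (0.13, 0.0987) the Notch call was lost. It was also lost, with larger medians, with the GAPDH ratio as a covariate (0.21, adjusted p = 0.0783) and without both ERbeta2 MO replicate 1 and coMO replicate 2 (0.25, adjusted p = 0.0721). The lateral line and hair cell list, closest to neuromasts, did not pass (adjusted p = 0.8), and its median of 0.06 and its mean of -0.03 had opposite signs. Of its 26 genes, pvalb8, a calcium-binding protein gene, was called lower (-1.36, SE 0.193, adjusted p = 0.0214). The neurogenesis list did not pass against coMO (median 0.16, adjusted p = 0.1). It passed without ERbeta2 MO replicate 1 (0.37, adjusted p = 0.000232) and without coMO replicate 1 (0.32, adjusted p = 0.0267), with the GAPDH ratio as a covariate (0.32, adjusted p = 0.0263) and without both ERbeta2 MO replicate 1 and coMO replicate 2 (0.30, adjusted p = 0.00483). Its median was -0.04 without ERbeta2 MO replicate 2.

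Other lists that did not pass against coMO were glia and myelin (median -0.27, adjusted p = 0.075), lens crystallin (-0.38, 0.075), hatching gland and yolk (-0.23, 0.1), pigment cell (0.39, 0.1), skeletal muscle (-0.21, 0.17), cell cycle (-0.09, 0.45), heart (-0.10, 0.47) and circadian clock (-0.13, 0.66). Within these, the myelin genes mbpa (-2.08) and cldnk (-1.18) and the glutamine synthetase gene glula (-0.95) were called lower (4 lower and 1 higher adjusted over the list alone), as were mttp (-1.08), a lipid transfer gene, agr2 and the cryptochrome gene cry3a (-1.24). Several of these lists passed when 1 array was left out, and the skeletal muscle list then passed in both directions: -0.53 (adjusted p = 2.56e-08) without ERbeta2 MO replicate 1, -0.38 (0.0181) without coMO replicate 1 and 0.18 (0.0358) without ERbeta2 MO replicate 2. Without ERbeta2 MO replicate 1, the lists of heart (-0.31, 0.0224), cell cycle (-0.18, 0.0456) and hatching gland and yolk (-0.54, 0.0375) passed, the last also without coMO replicate 1 (-0.63, 0.00474). Without ERbeta2 MO replicate 2, those of pigment cell (0.99, 7.95e-05), glia and myelin (-0.40, 0.0471), lens crystallin (-0.55, 0.0456) and estrogen response (-0.73, 0.0461) passed, and lens crystallin did so without coMO replicate 2 (-0.38, 0.0314). In fits that kept all arrays, skeletal muscle passed with the GAPDH ratio as a covariate (-0.29, 0.00974) and with 7751 probe sets tested (-0.24, 0.0459), lens crystallin with no filter (-0.29, 0.0409), and hatching gland and yolk with a pseudocount of 100 (-0.38, 0.0427). Skeletal muscle passed as well without both ERbeta2 MO replicate 1 and coMO replicate 2 (-0.39, 1.5e-09).

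Leaving out an uninjected array cannot alter the change between ERbeta2 MO and coMO. Where these groups do not overlap, no single array left out can turn the sign. The 264 calls depended on single arrays. Their number was 1 without coMO replicate 1, 0 without coMO replicate 2, 56 without either uninjected replicate, 599 without ERbeta2 MO replicate 1 and 1606 without ERbeta2 MO replicate 2, although all 264 kept their sign in each of these fits. With the log2 GAPDH ratio as a covariate no probe set was called by limma, where 771 had an unadjusted p under 0.05, and without both ERbeta2 MO replicate 1 and coMO replicate 2, which left 1 array of each group with the closest GAPDH ratios (2.01 and 1.95) beside both uninjected arrays (1.32 and 1.24), 793 were called; both settings were chosen after seeing the data, and hbbe3 and gnat2 then changed by 3.31 (SE 0.372) and -2.82 (SE 0.608) with the covariate. With each array centred on its median, the share of calls that were higher was 40.6% in place of 28.8%.

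The next question was how ERbeta2 MO embryos differed from embryos that were not injected. Pancreatic enzyme genes and cone genes were among the largest falls of named genes. The elastase gene ela2 had signals of 12 and 48.1 in ERbeta2 MO and 6313 and 1577 in uninjected embryos, and gnat2 was 33.1-fold, ctrb.1 27.9-fold, pde6c 20.8-fold and opn1mw1 20.3-fold lower. The gene hbbe3 was called higher, as were 12 of 33 neurogenesis and 8 of 26 Notch pathway genes. Both lists passed at a preset correlation but not with an estimated correlation (adjusted p = 0.58 and 0.54), and the neurogenesis list did not pass without ERbeta2 MO replicate 2 (adjusted p = 0.0919). The signals of hbbe3 were 3716 and 2678 in ERbeta2 MO and 10.6 and 8.55 in uninjected embryos, below the pseudocount of 32, so its log2 change of 6.26 was 8.23 with a pseudocount of 1 and 4.89 with 100. Among 11626 probe sets 2137 were called by limma, 960 higher and 1177 lower. The GAPDH ratio was 2.76 and 2.01 in ERbeta2 MO against 1.32 and 1.24 in uninjected embryos, and the acta1 ratio 8.92 and 13.5 against 3.54 and 4.26. With the GAPDH ratio as a covariate the list medians moved in both directions. Nearer to 0 were those of photoreceptor (-1.51), exocrine pancreas (-2.44), intestine (-1.49), liver (-1.07), ionocyte (-0.35), hatching gland and yolk (-0.61), cartilage and bone (-0.23), red blood cell (0.69) and Notch pathway (0.35). Further from 0 were those of neurogenesis (0.71), epidermis (-1.44), skeletal muscle (-0.64) and sterol synthesis (-0.57).

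The exocrine pancreas list had 15 of 17 genes called lower with a median log2 change of -3.69 (adjusted p = 1.4e-11, and adjusted p = 0.49 with an estimated correlation). Besides ela2 and ctrb.1, amy2a (-3.93) and ela3l (-3.91), an amylase and an elastase gene, were among the largest falls, together with gnb3b (-3.94), zgc:66156 (-4.04) and epd (-3.89). The photoreceptor list had 27 of 35 genes called lower and 2 higher (27 and 4 adjusted over the list alone), with a median of -2.70 (adjusted p = 1.9e-10, and adjusted p = 0.55 with an estimated correlation). The intestine list had 15 of 22 called lower, 19 adjusted over the list alone (median -1.51, adjusted p = 1.4e-11, and adjusted p = 0.43 with an estimated correlation), led by chia.2 (-3.45), vil1 (-3.37) and fabp2 (-3.34). The liver list had 21 of 38 called lower, 28 adjusted over the list alone (median -1.23, adjusted p = 8.1e-13, and adjusted p = 0.49 with an estimated correlation), led by fabp10a (-3.83), uox (-3.48) and the tryptophan dioxygenase gene tdo2a (-2.63). The epidermis list had 13 of 36 called lower, 19 adjusted over the list alone (median -0.94, adjusted p = 1.7e-08, and adjusted p = 0.55 with an estimated correlation), with the keratin genes krt15 (-2.95), krt1-19d (-2.65) and krt91 (-2.23), whose probe set shares its cluster name with those of other genes. The epidermis median was -1.42 without ERbeta2 MO replicate 1 and -0.41 without ERbeta2 MO replicate 2, and krt91 then changed by -1.37. The ionocyte list had 8 of 14 called lower, 9 adjusted over the list alone (median -0.81, adjusted p = 1.6e-05, and adjusted p = 0.43 with an estimated correlation), among them the carbonic anhydrase gene ca2 (-1.34) and the sodium pump genes atp1b2b (-1.71) and atp1a1a.4 (-1.43). The change of atp1b2b was -1.03 without ERbeta2 MO replicate 1.

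In the neurogenesis list 12 of 33 genes were called higher (15 adjusted over the list alone) and 0 lower, with a median of 0.53 (adjusted p = 0.00031, and adjusted p = 0.58 with an estimated correlation). The proneural gene neurog1 rose by 1.27 (SE 0.215, adjusted p = 0.0087) and sox11b by 1.31 (adjusted p = 0.00743). The neuronal gene elavl3 rose by 1.70 on the probe set used, but its 4 probe sets ranged from -0.47 to 1.70. Without ERbeta2 MO replicate 2 the list call was lost (median 0.22, adjusted p = 0.0919). The Notch pathway list had 8 of 26 genes called higher, and 9 higher and 1 lower adjusted over the list alone (median 0.46, adjusted p = 0.0037, and adjusted p = 0.54 with an estimated correlation), among them the ligand genes dlb (1.5) and dla (1.42) and the receptor genes notch1a (1.4) and notch3 (0.80, SE 0.223, adjusted p = 0.0399).

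The red blood cell list had 7 of 13 genes called higher, and 8 higher and 2 lower adjusted over the list alone (median 1.02, adjusted p = 6e-04, and adjusted p = 0.43 with an estimated correlation), including hbbe3 (6.26), slc4a1a (2.92) and the heme synthesis gene alas2 (1.59). Further rises were measured for bmb (3.41), rps27l (2.65), c6.2 (2.38), mmp9 (2.18), magi1b (1.99) and atf5b (1.78), and mmp9 changed by 1.35 without ERbeta2 MO replicate 1. The other magi1b probe set changed by 0.499 and was not called. Other lists that passed as lower were sterol synthesis (median -0.56, adjusted p = 0.0038), hatching gland and yolk (-0.83, 0.00053), cartilage and bone (-0.28, 0.0052) and skeletal muscle (-0.38, 0.0041). With an estimated correlation their adjusted p were 0.43, 0.46, 0.55 and 0.72. The cartilage call was lost without uninjected replicate 2 (median -0.20, adjusted p = 0.0652) and with the GAPDH ratio as a covariate (-0.23, 0.0974), and the muscle call without ERbeta2 MO replicate 2 (median -0.12, adjusted p = 0.673), whereas the muscle median was -0.76 without ERbeta2 MO replicate 1. Lists that had not passed but did so with 1 array left out were stress and heat shock (-0.48, 0.00267), heart (-0.84, 0.0338) and pigment cell (-1.06, 0.00624) without ERbeta2 MO replicate 1, and glia and myelin (-0.53, 0.0424) and estrogen response (-0.53, 0.0461) without ERbeta2 MO replicate 2. With the GAPDH ratio as a covariate, which kept all arrays, stress and heat shock (-0.53, 0.00418) and pigment cell (-0.91, 0.0123) passed too.

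In the lateral line and hair cell list, which did not pass (adjusted p = 0.63), pvalb8 was lower (-2.05) and 5 genes were called higher. Among these were pax2a (1.07) and sox3 (1.00) on the probe sets used. The other probe set changed by 0.0592 for pax2a and 0.149 for sox3, and neither was called. The sox3 probe set used shares its cluster name with those of other genes and its identity is in doubt. The count of 2137 was 61 without uninjected replicate 1 and 368 without uninjected replicate 2, and no probe set was called with the GAPDH ratio as a covariate, where 1057 had an unadjusted p under 0.05. It was 4429 without both ERbeta2 MO replicate 1 and coMO replicate 2, where the GAPDH ratios still differed (2.01 against 1.32 and 1.24), and the share of higher calls was 60.0% with median centring in place of 44.9%.

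**Figure D3:**
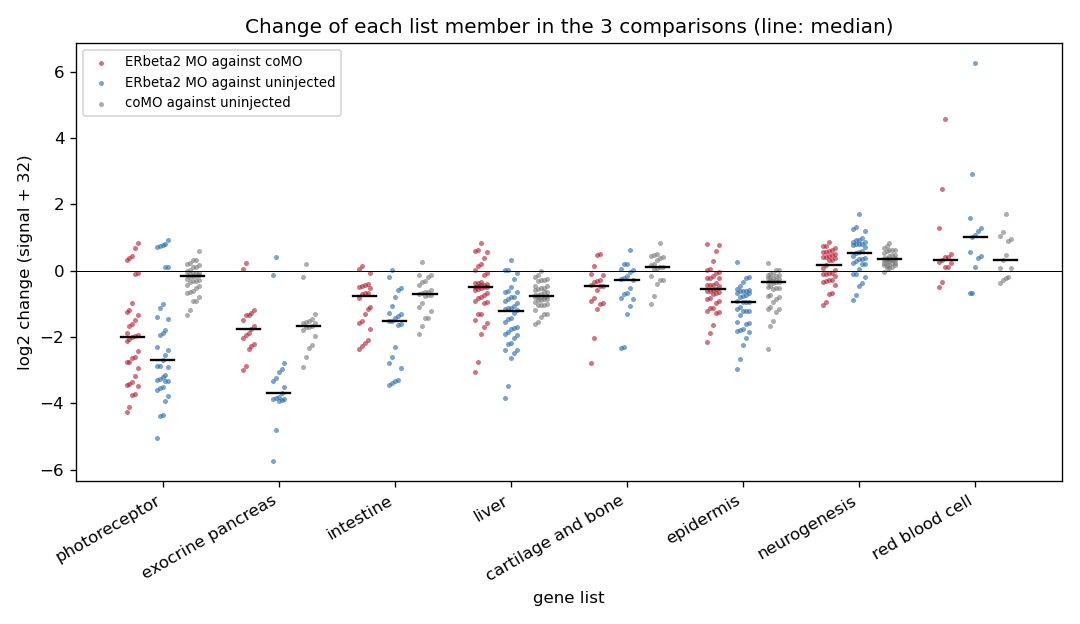
Points give the log2 change of each tested member of 8 gene lists in the 3 comparisons, and black lines the medians. The photoreceptor medians are -2.0 and -2.70 for ERbeta2 MO and -0.17 for coMO against uninjected, whereas the exocrine pancreas median is also low for coMO (-1.67).

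The last comparison asked what the control morpholino and the injection themselves changed. No probe set passed in coMO against uninjected with limma, where 1442 had an unadjusted p under 0.05 and 581 would have by chance, and the smallest adjusted p was 0.322. The count was 2 with only the 4 arrays compared. Fits with 1 coMO array, at a GAPDH ratio of 1.95 or 1.23, gave no spread for that group. They cannot show whether the changes follow that ratio, which was 1.32 and 1.24 in uninjected embryos. The 10 genes with the smallest unadjusted p had an adjusted p of 0.322 each, with changes of -1.60 for fthl28, whose probe set shares its cluster name with those of other genes, -1.53 for gjb8, -1.28 for pdk4, -1.68 for krt1-19d, -1.80 for adss1, -1.72 for ucp3, -1.15 for slc25a55b, 1.18 for crygmxl2, -1.23 for pla2g12b and 1.05 for nt5c2l1.

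No gene of the digestive organs was called in coMO embryos over all probe sets, but their lists passed as lower. The exocrine pancreas list had a median of -1.67 (adjusted p = 8e-13, and adjusted p = 0.49 with an estimated correlation), the liver list -0.77 (adjusted p = 1.9e-14, and adjusted p = 0.49 with an estimated correlation) and the intestine list -0.69 (adjusted p = 7.6e-09, and adjusted p = 0.43 with an estimated correlation). Adjusted over the list alone, 15, 7 and 9 genes were lower. The exocrine pancreas median was -1.09 without uninjected replicate 1 and the liver median -0.44 without coMO replicate 1. The photoreceptor list did not pass (median -0.17, adjusted p = 0.1), although it did without uninjected replicate 2 (-0.34, adjusted p = 0.0313), without ERbeta2 MO replicate 1 (adjusted p = 0.00329), without ERbeta2 MO replicate 2 (adjusted p = 0.00433), without both ERbeta2 MO replicate 1 and coMO replicate 2 (-0.25, adjusted p = 0.000369) and with a pseudocount of 100 (-0.14, adjusted p = 0.047), and its median was 0.05 with the GAPDH ratio as a covariate (adjusted p = 0.804). The neurogenesis list was higher (median 0.34, adjusted p = 3.1e-06, and adjusted p = 0.55 with an estimated correlation), as was the lens crystallin list (0.75, 4 genes higher adjusted over the list alone, adjusted p = 0.00031, and adjusted p = 0.43 with an estimated correlation), while the inflammation list was lower (-0.41, adjusted p = 0.00012, and adjusted p = 0.54 with an estimated correlation). The acta1 3'/5' ratio, 21.8 and 10.8 in coMO against 3.54 and 4.26 in uninjected embryos, moved with all of these groups.

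Further lists that passed as lower in coMO were epidermis (median -0.35, adjusted p = 8.7e-06), hatching gland and yolk (-0.39, 0.00014), ionocyte (-0.40, 6e-04), skeletal muscle (-0.28, 0.0028), pigment cell (-0.51, 0.013) and stress and heat shock (-0.14, 0.032). With an estimated correlation their adjusted p were 0.59, 0.43, 0.43, 0.72, 0.59 and 0.7. The red blood cell list (0.32, 0.009) and the Notch pathway list (0.24, 0.022) passed as higher, with an adjusted p of 0.46 and 0.55 with an estimated correlation. Without coMO replicate 1 the medians were -0.20 for epidermis, -0.26 for ionocyte and 0.18 for red blood cell, the last being 0.20 without uninjected replicate 1. Without coMO replicate 2 they were -0.58 for epidermis and -0.60 for hatching gland and yolk. With the GAPDH ratio as a covariate (1.95 and 1.23 against 1.32 and 1.24) they were -0.24 for ionocyte, 0.19 for red blood cell, -0.42 for skeletal muscle, -0.23 for stress and heat shock and -0.53 for epidermis. The muscle call was lost without coMO replicate 1 (median -0.17, adjusted p = 0.149). The stress and pigment calls were lost without coMO replicate 2, although the medians were then larger in size (-0.17, adjusted p = 0.0873, and -0.70, adjusted p = 0.123), and the pigment call also with 7751 probe sets tested (-0.49, 0.0943). The Notch call was lost without coMO replicate 1 (median 0.12, adjusted p = 0.115), without uninjected replicate 1 (0.12, 0.179), with no filter (0.21, 0.0576) and, with a larger median (0.30), without both ERbeta2 MO replicate 1 and coMO replicate 2 (0.0533), whereas the estrogen response list, which had not passed, did so without uninjected replicate 2 (-0.40, 0.0313).

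Across the 11626 probe sets, which are not independent replicates, the changes in ERbeta2 MO and in coMO, each against uninjected, had a Pearson correlation of 0.719 and a Spearman correlation of 0.689. All 6 arrays were also simulated as independent noise per probe set, with unchanged groups that share the uninjected arrays. The mean correlations were then 0.499 and 0.477. Correlation between probe sets was left out of the simulation, so it does not show how far 0.719 could arise without a change. The covariance was 0.212 against 0.0343 simulated, a difference of 0.178. The uninjected arrays could not be split into sets of 2, so part of the excess in correlation may come from them. Of the calls in ERbeta2 MO, 71 were higher and 182 lower against both coMO and uninjected, where independent lists would share 6.28 and 19, and the ERbeta2 MO arrays are common to both comparisons.

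The authors' deposited table of ERbeta2 MO over coMO listed 1046 probe sets, 494 with a ratio of at least 2 and 552 with a ratio of at most 0.498. Of the 957 that were tested, 955 had the same direction here, and the log2 ratios had a Pearson correlation of 0.979 across probe sets. The direction of that table as a whole was itself taken from its match with the value table. Ratios between 0.498 and 2 are absent from it, which raises such a correlation. The authors' deposited table held 250 of the 264 calls with the same direction, and 707 of its tested probe sets were not called. The authors' deposited table gave 45.66 for hbbe3 and 0.0423 for gnat2 in this comparison. Against uninjected embryos the authors' deposited tables listed 2443 probe sets for ERbeta2 MO and 541 for coMO.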

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

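The tests in this part were chosen after the results were seen, apart from median centring, which was a planned setting. Control probe sets, which enter none of the comparisons, gave signals above the uninjected arrays on both arrays of a group. The mean GAPDH 3'/5' ratio was 2.38 in ERbeta2 MO, where the uninjected arrays gave 1.24 and 1.32. The mean acta1 3'/5' ratio was 11.2 in ERbeta2 MO and 16.3 in coMO, against 3.54 and 4.26 in uninjected embryos. The geometric mean of the poly-A spike-in probe sets was 617 in ERbeta2 MO, against 265 and 340, and that of the hybridization spike-ins was 2050 against 1380 and 1660. On the log2 scale and over arrays, the 95% interval of the acta1 difference between coMO and uninjected embryos lay above 0 (0.411 to 3.55). For ERbeta2 MO against uninjected embryos the intervals included 0 for GAPDH (-0.179 to 1.93), acta1 (-0.072 to 3.07), the poly-A spike-ins (-0.472 to 2.44) and the hybridization spike-ins (-0.175 to 1.04), with 3 residual degrees of freedom.

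Photoreceptor genes were lower in ERbeta2 MO than in coMO, with a mean change of -1.94 over the list's members (95% interval -3.69 to -0.188 over arrays). A scaling difference that shifts whole arrays is argued against. Centring each array on its median moved the median change of all probe sets by 0.0721 here and left the list median at -1.93. Differences between arrays that depend on intensity are not tested by such a shift. Lower RNA integrity of the ERbeta2 MO arrays stays open, with an acta1 ratio that differed from coMO by -0.483 on the log2 scale (95% interval -2.05 to 1.09): with the GAPDH ratio as a covariate the mean change was -1.26 with a 95% interval of -4.35 to 1.84, the SE going from 0.549 to 0.72 with 2 residual degrees of freedom, so the smaller change, the larger error and the fewer degrees of freedom took the interval past 0. The list still passed against other genes with the covariate (median -1.23, adjusted p = 4.74e-12) and with the ERbeta2 MO and coMO arrays of closest ratio, 2.01 and 1.95 (median -1.17, adjusted p = 1.84e-21), but the latter are single arrays and neither median gives an error between arrays. A delay of development may also account for late genes being low and stays open, as the neurogenesis list, whose median against coMO was 0.164, did not pass with all arrays and no covariate, passed with the covariate (0.323, adjusted p = 0.0263), and had a median of -0.0401 without ERbeta2 MO replicate 2, and no series of stages was analysed here. A loss of ERbeta2, the biological difference that the design names, also stays open and untested, since 1 morpholino was used.

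The rise of hbbe3 against coMO was 4.56 (95% interval 3.46 to 5.66). Whether more red blood cells account for it is not settled. The change of hbbe3 exceeded the mean change of the 12 other red blood cell genes by 4.12 (95% interval 1.86 to 6.38 over arrays). But hbbe3 was picked as the largest rise, which that interval does not allow for. In the list 3 of 13 genes, hbbe3, slc4a1a and hbaa1, were called higher and 10 were not called. Signal of hbbe2 on the hbbe3 probe set is argued against, since hbbe2 changed by 0.117 (95% interval -0.44 to 0.673). Lower RNA integrity, as far as the GAPDH ratio tracks it, is argued against as the whole cause, since with that ratio as a covariate the change was 3.31 (SE 0.439, 95% interval 1.42 to 5.19 over arrays) against 4.56 (SE 0.73, 2.24 to 6.89) without it, though a part of the change stays open and the gene was no longer called (adjusted p = 0.261) in a fit with 2 residual degrees of freedom that called no probe set by limma, where 771 had an unadjusted p under 0.05. Signal from other globin transcripts and a switch among globin genes were not tested, as probe sequences were not used here.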

How the results depend on the processing

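The GAPDH covariate and the reduced set of arrays (ERbeta2 MO replicate 2 and coMO replicate 1, whose ratios were closest, with both uninjected arrays, whose ratios were lower) were chosen after seeing the data; the other settings were planned. Called genes named in the text kept their direction in every setting run. Why results differed between settings was not tested. For the largest rises and falls, chosen among groups that do not overlap, leaving out 1 array could not turn the direction. The count of 264 calls against coMO was 129 with no filter, 59 with only the 4 arrays compared, 141 with the replicate number as a block, 0 with the covariate and 793 with the reduced set, and 0 to 1606 when 1 array was left out. The count of 2137 calls in ERbeta2 MO against uninjected was 0 with the covariate and 4429 with the reduced set, and 61 to 3148 with 1 array left out. For coMO against uninjected, with no calls, the counts were 2 with only the 4 arrays, 2165 with the reduced set and 0 to 9 with 1 array left out. A fit that leaves 1 array in a group assumes that it varies like the others. Deviations of replicates with the same number had correlations across probe sets of -0.0849, 0.111 and -0.0959. These values have no reference here, so whether the numbers pair the samples stays open. Under the block the coMO photoreceptor list also passed with camera (adjusted p = 0.0486, median -0.17).

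The number of lists called was 13, 14 and 14 in the 3 comparisons, in the order ERbeta2 MO against coMO, ERbeta2 MO against uninjected, and coMO against uninjected. It was 0, 0 and 0 with an estimated correlation and 1, 4 and 0 with fry, which tests whether a list's genes move one way without comparing them with others. With 1 array left out it was 13 to 17, 12 to 16 and 12 to 16. The lists called with fry were sterol synthesis in both comparisons of ERbeta2 MO, and also intestine, red blood cell and ionocyte against uninjected. Of the named genes, 51, 79 and 0 were called. Against coMO the number was 19 with only the 4 arrays and 0 with the covariate, against uninjected 0 with the covariate, and for coMO 10 with the reduced set. With 1 array left out it was 0 to 51, 19 to 78 and 0 to 2. The correlation of 0.719 across probe sets was 0.567 to 0.770 with 1 array left out. The robust setting does not apply to camera and lists were not run with only the 4 arrays; the interferon list has no value with 7751 probe sets tested, as no member was left.

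Some list medians, most of them near 0, had the opposite sign in a setting. In ERbeta2 MO against coMO, stress and heat shock was 0.0233 with median centring, and heart 0.0407 with 7751 probe sets tested. With the covariate, estrogen response was 0.0258, pigment cell -0.149 and hatching gland and yolk 0.0677. With the reduced set, estrogen response was 0.126, pigment cell -0.166 and circadian clock 0.0316. In ERbeta2 MO against uninjected, inflammation was 0.0652 with median centring, 0.105 with quantile normalization and 0.103 with 7751 probe sets, and cell cycle 0.0409 with median centring and 0.0112 with quantile normalization. Lateral line and hair cell was -0.0279 with 7751 probe sets. Estrogen response was 0.251 with the covariate and 0.15 with the reduced set, where interferon was -0.0354. In coMO against uninjected, glia and myelin was 0.0233 with median centring and 0.0592 with the covariate, photoreceptor 0.0535 and circadian clock 0.0116 with the covariate, and lateral line and hair cell -0.0129 with no filter.

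With 1 array left out, medians that changed sign against coMO ranged from -0.731 to 0.0127 for estrogen response, -0.026 to 0.209 for lateral line and hair cell, -0.0401 to 0.367 for neurogenesis, -0.244 to 0.123 for stress and heat shock and -0.181 to 0.0123 for cell cycle. They ranged from -0.311 to 0.14 for heart, -0.526 to 0.177 for skeletal muscle, -0.185 to 0.989 for pigment cell, -0.63 to 0.159 for hatching gland and yolk, -1.08 to 0.0122 for epidermis and -0.148 to 0.0488 for circadian clock. Those of ERbeta2 MO against uninjected ranged from -0.529 to 0.15 for estrogen response, -0.00886 to 0.133 for lateral line and hair cell, -0.0354 to 0.352 for interferon, -0.427 to 0.00745 for inflammation, -0.84 to 0.185 for heart and -1.06 to 0.337 for pigment cell. Those of coMO against uninjected ranged from -0.176 to 0.0292 for glia and myelin and -0.0215 to 0.121 for cell cycle.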
